A study of Mus musculus with 22 samples.

How the data were processed

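RNA was sequenced from 22 libraries, an immunoprecipitate (IP) and an input from each of 11 mice. The tissue was the arcuate nucleus and median eminence of the hypothalamus. Per the labels' protocols, ribosomes were captured with an antibody to ribosomal protein S6 phosphorylated at serines 244 and 247 (phosphoTRAP), and the input was a portion of the same homogenate set aside before the antibody was added. The mice were MCH-hM3Dq mice (4 mice, numbered 1, 3, 4 and 5) or control mice (7 mice, numbered 1 to 7). Per the labels, the mice were 10 to 13 weeks old, on a C57BL/6N background, fasted for 12 h and given the receptor's ligand clozapine N-oxide (CNO) 1 h before collection. The series' design names 5 hM3Dq mice, of which 4 were analysed here.

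All values came from 1 table deposited by the authors, which gives a normalized FPKM (fragments scaled by transcript length and library size) for each of 17440 genes in each library. Per the submitters' processing notes, HISAT2 2.1.0 and StringTie 1.3.4d were used with build GRCm38.p6. The method that normalized the FPKM is not named in the labels, the notes or the table. The column sums differed between libraries, and 4.05% of the FPKM values were exact zeros and 1.18% lay above 0 but under 1e-06. The table also holds, per mouse, a ratio of IP FPKM over input FPKM, which the authors left blank where either value was 0. Each filled ratio was checked to equal the IP value over the input value within 0.1%. The authors also deposited a p-value per gene, which equals a two-sided unequal-variance test of the ratios between genotypes within 0.1% in all 17440 genes. The deposited log2 fold change equals the log2 of the mean hM3Dq ratio over the mean control ratio, and no adjusted p-value is given. The table lists genes with at least 2 ratios in each genotype, so a gene with many zeros in the 4 hM3Dq mice is less easily listed than one with as many in the 7 control mice. The ratios, p-values and fold changes of the authors were used only where the text says so.

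Gene identifiers were matched to GENCODE mouse release 21 (GRCm38) for symbols, positions and transcript lengths. All 17440 genes matched, and 17435 had a transcript length, taken from the longest annotated transcript of each gene. The number of reads per library is unknown, because the table holds no counts. Steps of whole reads are visible among the low FPKM values, and the ratio of these steps between libraries gave each library's depth relative to the others. The estimates for 229 of the 231 library pairs agreed within 0.1 on the log2 scale, and relative depth ran from 0.686 to 1.27, a 1.85-fold range.

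Values were analysed as log2(FPKM + 1). In each comparison, genes with an FPKM of 1 or more in at least 4 of the libraries compared were tested with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p-value under 0.05 were called. There were 5 comparisons: IP between genotypes, input between genotypes, IP against input within the control mice, IP against input within the hM3Dq mice, and the IP over input difference per mouse between genotypes. IP and input of a mouse were paired by mouse in the within-genotype comparisons. Comparisons between genotypes were not paired, because the numbers shared by hM3Dq and control mice name different animals. Tests were two-sided. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

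Before the data were examined, 32 gene lists were fixed. One held immediate early genes. Cell type lists covered lateral hypothalamic peptide neurons, AgRP neurons, POMC neurons, kisspeptin and tachykinin neurons, arcuate dopamine neurons, other arcuate peptide neurons, ventromedial hypothalamic neurons, pan-neuronal genes, tanycytes, ependymal cells, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and macrophages, endothelial cells, mural cells, vascular leptomeningeal cells, pars tuberalis and pituitary, choroid plexus and erythroid cells. The remaining lists were VEGF and angiogenic signalling, tight junctions and barrier, cytosolic ribosomal proteins, translation factors, mitochondrially encoded proteins, nuclear oxidative phosphorylation subunits, long noncoding nuclear RNAs, heat shock and endoplasmic reticulum stress, glucocorticoid and fasting response, circadian clock and sex-linked genes. Lists with 3 or more tested genes were compared with all other genes by limma's camera with the correlation between genes estimated from the data, and adjusted over the lists of a comparison. Member genes were counted as passing over all genes tested and, separately, when adjusted over the list alone.

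The genes named in the text were chosen by a rule fixed before the data were examined. In each comparison these were the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with a mean FPKM of at least 5 in the higher group. Where fewer than 10 genes passed, the 10 with the smallest p-values at that level were named as well. Up to 4 members of each list with the smallest p-values were added, as were Pmch, Mchr1, Chrm3, Fos, Agrp, Npy, Pomc, Vegfa, Plvap and Rax in every comparison. Genes known only by an identifier or a provisional symbol, pseudogenes and the 13 symbols with several entries were left out of the first part of the rule. Any gene named outside the rule is said to be so.

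The gene and list tests were tested on simulated data with known changes. With 100 genes changed by 1 and 100 by 2 on the log2 scale, the IP comparison between genotypes recovered 49% and 78%, the input comparison 19% and 75%, the control IP against input comparison 30% and 81%, the hM3Dq one 11% and 80%, and the comparison of differences per mouse 7% and 58%. A simulated list of 15 raised genes was called in every comparison except IP against input in the hM3Dq mice, where its camera adjusted p was 0.0942, and 0 of 30 random lists were called by camera in any comparison. The simulated genes were drawn independently of each other, with no effect of mouse. Genes of the real lists are correlated, so these simulated lists do not show how often camera finds or misses such lists. Alternatives run for the gene counts and the named genes were a pseudocount of 0.1, no filter on low values, a filter at an FPKM of 5, median-of-ratios rescaling, quantile normalization, eBayes without the trend, 1 fit of all 22 libraries, the comparison with or without a block on mouse or mouse number, and each mouse left out in turn. The lists were rerun with a preset correlation of 0.01, median-of-ratios rescaling and quantile normalization only. Further fits without libraries that stood apart, of genes and lists, were chosen after the data were seen.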

Results

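PhosphoTRAP enriches messenger RNA on ribosomes whose S6 protein is phosphorylated, a mark that rises in active neurons. It was applied here to the arcuate nucleus and median eminence after CNO in mice that express the activating receptor hM3Dq in neurons making melanin-concentrating hormone (MCH), and in control mice. The series addresses which transcripts respond when MCH neurons are activated. There were 4 IP and 4 input libraries from hM3Dq mice and 7 IP and 7 input libraries from control mice. Genes with an FPKM of 1 or more numbered 12812 ± 115 (SD, n = 4) in hM3Dq IP, 12853 ± 277 (SD, n = 7) in control IP, 12806 ± 132 (SD, n = 4) in hM3Dq input and 12640 ± 222 (SD, n = 7) in control input. Relative depth averaged 1.02 ± 0.0808, 1.14 ± 0.126, 0.975 ± 0.0558 and 0.9 ± 0.171 in the same order, while the number of reads behind them is unknown. All 22 libraries expressed the Y-linked gene Ddx3y at an FPKM of 19.9 or more, as male tissue does. The first principal component, with 17.25% of the variance, separated IP from input.

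3 control libraries stood apart from their groups. The IP of control mouse 5 had 1515 genes at 0 and a mitochondrially encoded share of 0.64% of its summed FPKM, against 0.154% ± 0.217 (SD, n = 7) over the control IPs. That share counts only the mitochondrially encoded protein genes with deposited values. The median correlation of this IP with the other control IPs was 0.887. The inputs of control mice 1 and 6 had 1895 and 1579 genes at 0. Control mouse 5 differed from the other control mice in several gene groups described below.

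Pmch, which encodes the MCH precursor, was abundant in both fractions. It (ENSMUSG00000035383, GRCm38 chromosome 10, 88091072 to 88092375) averaged an FPKM of 279 ± 154 (SD, n = 4) in hM3Dq IP, 320 ± 186 (SD, n = 7) in control IP, 174 ± 119 (SD, n = 4) in hM3Dq input and 290.3 ± 151 (SD, n = 7) in control input. No difference between the genotypes in Pmch passed the test in either fraction. The Pmch locus overlaps Parpbp on the opposite strand. Both genes are on the lateral hypothalamic peptide neuron list, so these 2 members may not be separate measures. The hM3Dq receptor derives from the human muscarinic receptor gene, so the mouse Chrm3 values (2.33 ± 1.53 in hM3Dq IP and 1.9 ± 1.77 in control IP) do not measure the transgene and do not check the genotype labels.

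**Figure D1:**
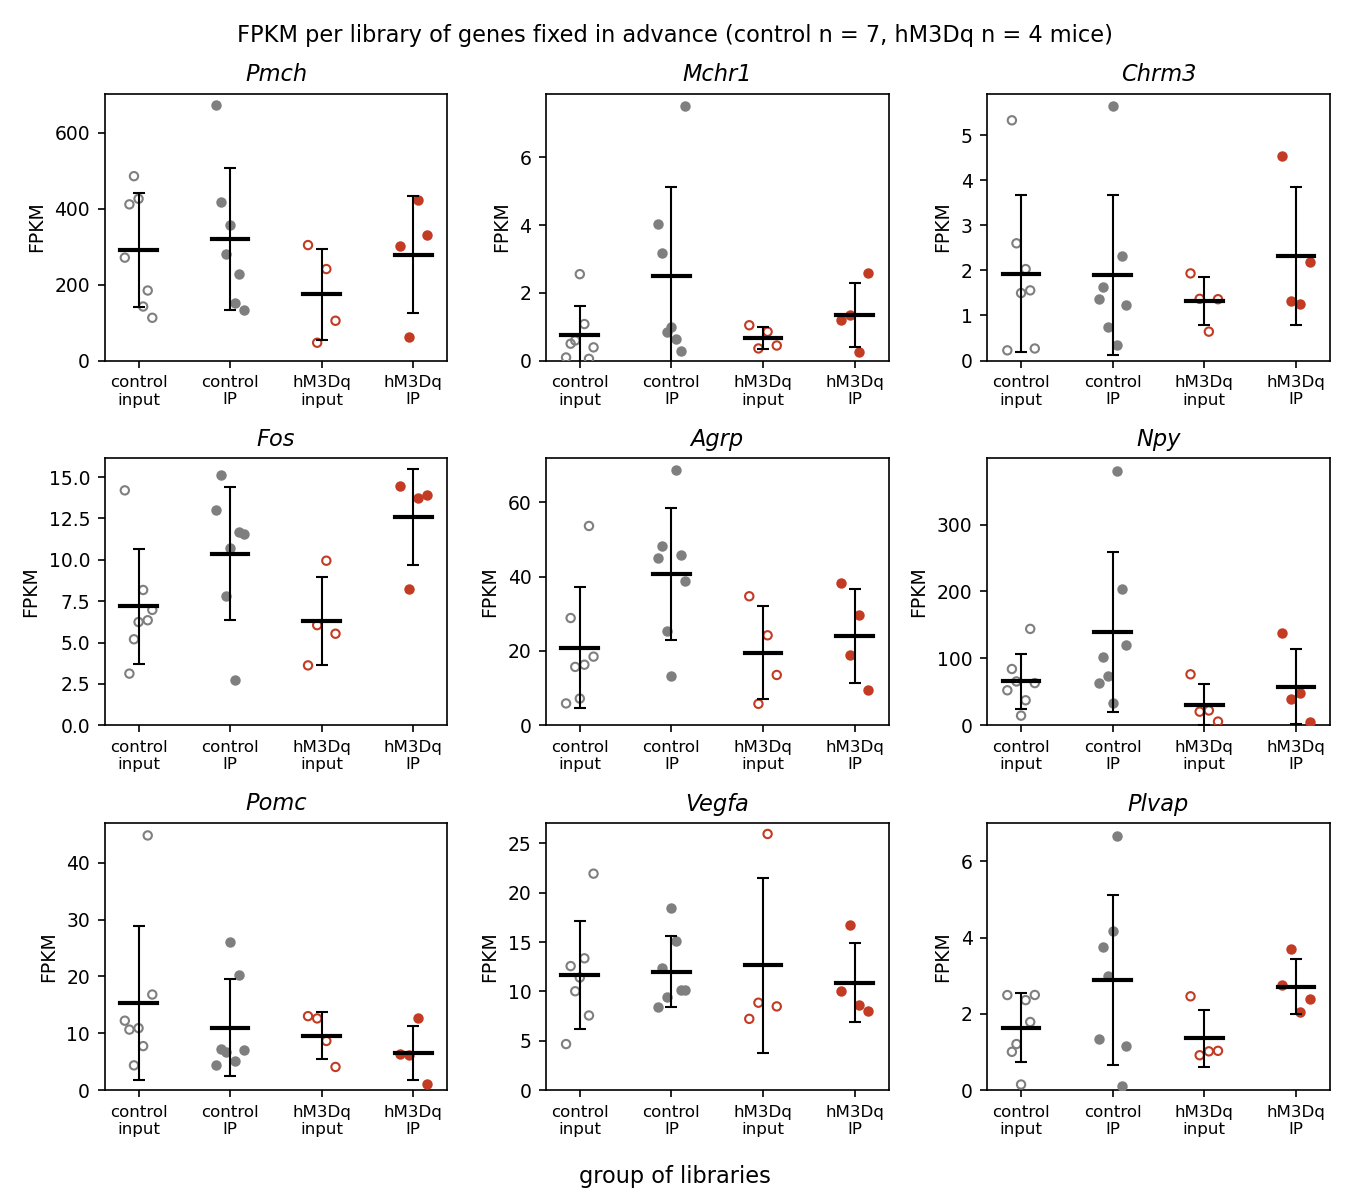
FPKM (vertical axes, each starting at 0) of 9 genes fixed in advance in every library, by group of libraries (open circles, input; filled circles, IP; grey, 7 control mice; red, 4 hM3Dq mice), with bars for mean and SD. Fos sat between 13.73 and 14.44 in 3 of the 4 hM3Dq IPs and at 8.247 in the fourth, and for each gene the hM3Dq and control mice overlapped in both fractions.

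What the pS6 pulldown retained was asked first, by comparing IP with input of the same mouse. In the control mice, activity-regulated genes and neuronal genes were higher in the IP, while many transcripts of ribosomal proteins, mitochondrially encoded RNAs and some structural noncoding RNAs were lower. Of 13999 genes tested, limma called 678, of which 312 were higher and 366 lower in the IP, and 91 and 200 of these differed by at least 1 on the log2 scale. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), an AP-1 transcription factor induced by neuronal activity, rose by 1.69 on the log2 scale (SE 0.267, limma adjusted p = 0.00389, higher in 7 of 7 mice), from an FPKM of 1.4 ± 0.616 in input to 6.87 ± 2.6 in IP (SD, n = 7). Bc1 (ENSMUSG00000115783, chromosome 7, 144914470 to 144914637), a short noncoding RNA of neurons, fell by 9.50 (SE 0.389, limma adjusted p = 4.13e-08, lower in 7 of 7 mice).

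Among the 10 largest increases in the control IP were Fam3a (1.81), the stress-inducible gene Gadd45b (1.78), the calcitonin receptor-like receptor gene Calcrl (1.76) and Fosb. The others were Mum1l1 (1.68), the beta-globin gene Hbb-bt (1.60), Haus4 (1.57), the osteopontin gene Spp1 (1.56), Nexn (1.54) and the glycolytic gene Gapdh (1.51). The Haus4 call was kept under 7 of 15 alternatives and the Spp1 call under 4 of 14. Each of the 10 was higher in at least 6 of 7 mice, and their limma adjusted p-values ran from 0.00389 to 0.0413. The 10 largest decreases were Bc1, the 7SK RNA Rn7sk (−5.84), Ccnb1ip1 (−5.44), the mitochondrial methionine tRNA gene mt-Tm (−5.28) and 6 protein-coding mitochondrial genes between mt-Nd1 (−5.79) and mt-Nd4l (−5.08). Rn7sk alone made up 8.14% ± 2.93 of the summed input FPKM and 0.17% ± 0.0932 of the IP (SD, n = 7). The Ccnb1ip1 locus (chromosome 14, 50789248 to 50807732) overlaps on the same strand the gene of the RNase P RNA, Rpph1 (50807449 to 50807767), which the table does not list, so the table cannot show which of the 2 genes the Ccnb1ip1 values here and below measure.

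The immediate early gene list was called in the control mice, though not when control mice 1, 5 and 6 were left out. In that smaller fit its median was 0.698, with 23 of 26 members positive, against 0.564 with all mice. The call was thus lost although the median was larger, and why it was lost was not tested. With all 7 mice, 8 of 30 tested members rose and 0 fell by limma over all genes tested. Of the 30, 13 had an unadjusted p under 0.05, and 13 rose when adjusted over the list alone. The list ranked above other genes (camera adjusted p = 0.0266, median log2 fold change 0.56). Besides Fosb, Jun rose by 1.25, Fosl2 by 1.29 and Egr3 by 1.32, all transcription factors of the early response to activity. Each of the 7 control mice had a mean IP over input above 0 for this list, at 0.56 ± 0.0537 (SD, n = 7). The pan-neuronal list was the other list called, likewise not without those 3 mice. Its median was 0.501 without them, with 17 of 19 members positive, and 0.365 with all mice. With all mice, 4 of 19 members rose (10 adjusted over the list alone, camera adjusted p = 0.0266). They were the synaptic genes Syt1 (0.67) and Snap25 (0.47), the neurofilament gene Nefm (0.75) and the secretogranin gene Scg2 (0.56), of which the Snap25 call was kept under 5 of 16 alternatives and the Scg2 call under 8.

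Many translation machinery transcripts were lower in the control IP. Of 77 ribosomal protein genes, 45 fell and 0 rose by limma over all genes, and 61 fell adjusted over the list alone, with a median of −0.78. Rps3 fell by 1.31, Rps27 by 1.66, Rpl13a by 1.80 and Rps4x by 1.13. Of 12 translation factor genes, 5 fell (7 adjusted over the list alone), including Eef1g (−1.34), Eif4a2 (−1.06), Eif3f (−0.82) and Eef1b2 (−0.73). The set test did not call either list (camera adjusted p = 0.214 and 0.201). Both lists had a mean IP over input below 0 in all control mice except mouse 5 for the ribosomal proteins, which stood at 0.12 against −0.77 ± 0.533 (SD, n = 7). All 9 mitochondrially encoded protein genes with deposited values fell (camera adjusted p = 0.0507), with a median of −5.14, and in mouse 5 their mean was −2.68. Of 5 long noncoding nuclear RNAs, 3 fell over all genes, Snhg11 by 1.21, Miat by 1.32 and Neat1 by 1.16, and 5 fell adjusted over the list alone (camera adjusted p = 0.0507), but the Neat1 call was kept under 5 of 16 alternatives.

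In the control mice the called oligodendrocyte genes were lower and the called erythroid genes higher in the IP, without a call of either list. Of 13 oligodendrocyte genes, 4 fell over all genes and over the list alone, among them the myelin genes Mobp (−0.68), Mbp (−0.48) and Mal (−0.95), with a camera adjusted p of 0.346 and a mean of −1.49 in mouse 5. Among 5 erythroid genes, 3 rose (4 adjusted over the list alone), the globins Hbb-bt, Hbb-bs (1.25) and Hba-a2 (1.23), with a camera adjusted p of 0.214. Single members passed in other lists: the ependymal gene Ccdc153 fell by 1.37, the astrocyte gene S100b fell by 0.63, and Ndufa2 of the oxidative phosphorylation list fell by 0.60. Lateral hypothalamic peptide, kisspeptin and tachykinin, dopamine, ventromedial, tanycyte, endothelial, mural, choroid plexus, tight junction and sex-linked genes had 0 members past the limma test over all genes in either genotype. Agrp, a peptide of hunger-promoting neurons, rose by 1.10 (SE 0.291, limma adjusted p = 0.0494, higher in 6 of 7 mice), and Tbx3 of the POMC neuron list rose by 1.05. The AgRP neuron list had its highest control mean IP over input in mouse 5, at 1.61, and its next highest in mouse 1, at 0.639. The annotated Agrp locus overlaps other genes on both strands. Of 16 alternatives, 3 kept the Mbp and Mal calls, 4 the Agrp call, 7 the S100b, Ndufa2 and Tbx3 calls and 8 the Hbb-bs call.

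The count in the control mice depended on which mice were used. Leaving out control mouse 2, 3, 4, 6 or 7 gave 330, 381, 338, 433 or 381 called genes, and leaving out mouse 1 or 5 gave 718 or 768. With eBayes without the trend there were 312, and 1 fit of all libraries gave 1395. Without control mice 1, 5 and 6 there were 716, of which 436 were among the 678, and 0 of 30 lists were called by camera, with 5 at an unadjusted p under 0.05. The medians of the 2 lists called with all mice were larger in that fit. They were 0.698 against 0.564 for immediate early genes and 0.501 against 0.365 for pan-neuronal genes. Medians also grew for ribosomal proteins, to −0.882 from −0.78, and erythroid cells, to 1.47 from 1.23. Medians of some other lists shrank, to −0.186 from −0.479 for oligodendrocytes, to 0.126 from 0.517 for AgRP neurons and to −0.0631 from −0.214 for astrocytes.

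In the hM3Dq mice, structural noncoding and mitochondrially encoded RNAs were again the most depleted from the IP, and 11 of 26 immediate early and 6 of 19 pan-neuronal genes rose, without a call of either list (camera adjusted p = 0.18 and 0.115). Limma called 1338 of 12987 genes, 702 higher and 636 lower in the IP, and 171 and 289 of these differed by at least 1 on the log2 scale. The largest decreases were Bc1 (−10.86), Rn7sk (−7.81), Ccnb1ip1 (−7.41), mt-Nd1 (−6.74) and Rmrp (−6.26), the RNA of RNase MRP. They were followed by mt-Nd2, mt-Cytb, mt-Co1, mt-Atp8 and mt-Nd6 between −6.21 and −5.45, and all 10 were lower in 4 of 4 mice. The largest increases were Zeb2os (2.13), an antisense transcript of Zeb2, the inhibitory-synapse gene Nlgn2 (1.99), Zc3h13 (1.83), Auts2 (1.80), Hivep2 (1.62) and Fosb (1.60). Nav1 (1.59), Exoc3l (1.59), Fam13b (1.58) and the potassium channel gene Kcna4 (1.57) completed the 10, with limma adjusted p-values from 0.00143 to 0.0384. All but Zeb2os, at 3 of 4, were higher in 4 of 4 mice, and the Zeb2os call was kept under 5 of 10 alternatives and the Auts2 call under 4 of 8. Leaving out hM3Dq mouse 1, 3, 4 or 5 gave 575, 599, 706 or 836 called genes. Without the filter, the trend or the pairing by mouse the count was 552, 592 or 739, and 678 in 1 fit of all libraries.

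Single immediate early genes were higher in the hM3Dq IP, though the list was not called (camera adjusted p = 0.18). Of 26 tested members, 11 rose (13 adjusted over the list alone) and 0 fell by limma, while 13 had an unadjusted p under 0.05. Jun rose by 1.43, Fosl2 by 0.94 and Nr4a3, a nuclear receptor gene of the early response, by 1.22. The list's mean IP over input was 0.59 ± 0.127 (SD, n = 4), above 0 in 4 of 4 mice. Of 19 pan-neuronal genes, 6 rose (14 adjusted over the list alone, camera adjusted p = 0.115), among them Syt1 (0.69), Elavl2 (0.66), Rbfox3 (0.70) and Nefl (0.50), the last kept under 4 of 12 alternatives. Fos had a log2 fold change of 0.94 (SE 0.262, limma adjusted p = 0.0505, higher in 4 of 4 mice) and did not pass, and it passed with a filter at an FPKM of 5 and with quantile normalization. Of 77 ribosomal protein genes, 68 fell and 0 rose over all genes (72 fell adjusted over the list alone), with a median of −0.96, including Rps21 (−1.57), Rpl13a (−1.70) and Rps12 (−1.79). Of 12 translation factor genes 8 fell over all genes and over the list alone, such as Eef1b2 (−1.19), Eif4a2 (−1.16) and Eef1g (−1.11).

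All 9 mitochondrially encoded protein genes with deposited values fell in the hM3Dq IP, with a median of −5.62. Of 5 long noncoding nuclear RNAs, 4 fell over all genes and over the list alone, Snhg11 by 1.31, Neat1 by 1.42, Miat by 1.10 and Mirg by 1.32. Of 12 oligodendrocyte genes, 4 fell over all genes and over the list alone, among them Mobp by 0.95, Mbp by 0.73 and Mog by 0.97. Single members passed elsewhere: Ghrh, the growth hormone-releasing hormone gene, rose by 1.17, the oligodendrocyte precursor gene Pdgfra by 0.92 and the globin Hbb-bs by 0.93. The microglial gene Tyrobp fell by 0.89 and Vegfb fell by 0.78. Of the nuclear oxidative phosphorylation subunits, Ndufs1 (0.88) and Ndufs5 (0.61) rose and Cox8a (−0.49) fell. Of 12 alternatives, 3 kept the Cox8a call, 5 the Mog call and 6 the Vegfb call, and of 11, 4 kept the Pdgfra call and 5 the Miat call. Camera called 0 of 30 lists in these mice, with 6 at an unadjusted p under 0.05 and the smallest adjusted p, 0.115, shared by the pan-neuronal, ribosomal protein, translation factor and mitochondrially encoded lists. The immediate early gene list stood at 0.18. The same test missed a simulated list in this comparison. Its genes were drawn independently and with no effect of mouse, so that miss does not show how often real lists are missed here. The per-mouse means of the immediate early gene list did not differ detectably between genotypes (exact permutation p = 0.603, Benjamini-Hochberg adjusted p = 0.982 over 31 lists).

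Agrp in the control mice was the only call between IP and input among the genes fixed in advance. In control and hM3Dq mice the log2 fold changes were 1.10 and 0.37 for Agrp, 0.94 and 0.70 for Npy, −0.41 and −0.67 for Pomc, 0.13 and 0.71 for Pmch and 0.80 and 0.41 for Mchr1. They were 0.46 and 0.94 for Fos, 0.11 and −0.07 for Vegfa, 0.41 and 0.69 for Plvap and 0.01 and 0.45 for Chrm3. Apart from Agrp in control mice, the limma adjusted p-values ran from 0.113 to 0.994 in control and from 0.0505 to 0.925 in hM3Dq mice.

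**Figure D2:**
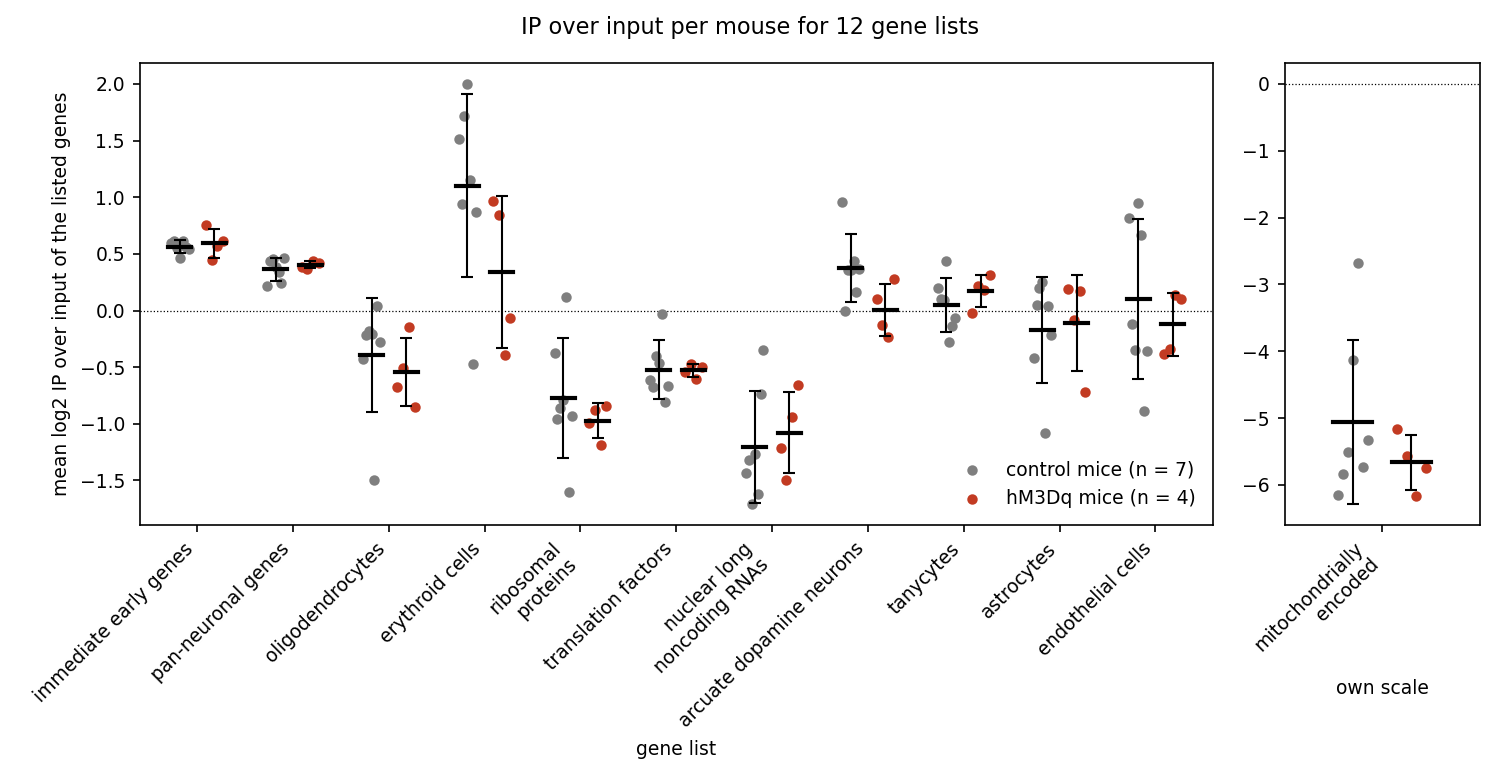
Mean log2 IP over input (vertical axis) of the genes of 12 lists (horizontal axis), 1 point per mouse (grey, 7 control mice; red, 4 hM3Dq mice), with bars for mean and SD and a separate scale for the mitochondrially encoded genes. Immediate early genes were above 0 in all 11 mice, at 0.56 ± 0.0537 in control and 0.59 ± 0.127 in hM3Dq mice, and mitochondrially encoded genes were below 0 in all 11.

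The genes retained or depleted by the pulldown overlapped between the genotypes, which share no library. Of 12891 genes tested in both, 305 were higher in the control IP and 702 in the hM3Dq IP, and 194 were higher in both, against 16.6 if the calls were independent. Lower genes numbered 362 and 635, with 282 in both against 17.8. Of the genes called in the control mice, 298 of the higher and 360 of the lower ones had the same sign and 0 were called in the opposite direction in the hM3Dq mice. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.688 and a Spearman rho of 0.565.

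**Figure D3:**
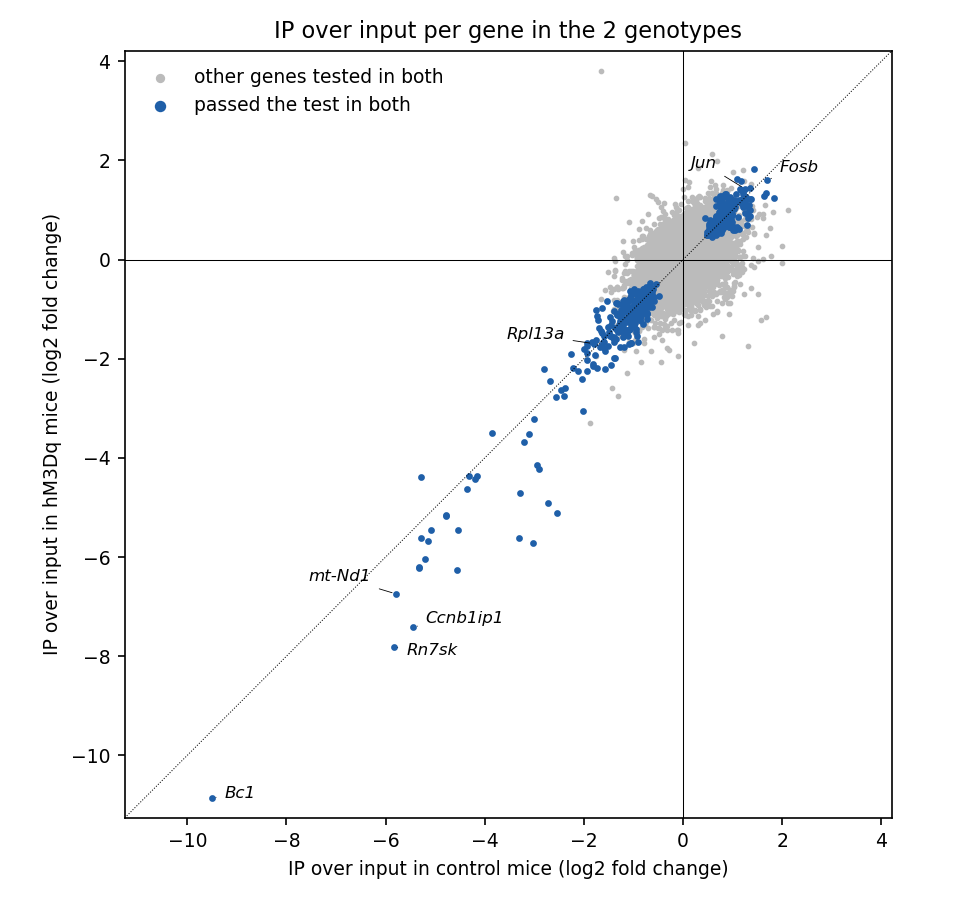
Log2 fold change of IP over input per gene in control mice (horizontal axis) and hM3Dq mice (vertical axis) for 12891 genes tested in both, with genes called in both in blue, others in grey and a dotted line of equal values. Bc1, Rn7sk, Ccnb1ip1 and mt-Nd1 lie far below 0 in both genotypes, and Fosb and Jun lie above 0 in both.

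Comparing the IP of hM3Dq mice with the IP of control mice asks which transcripts on phosphorylated ribosomes differ after MCH neuron activation. The only gene that passed the test, Gm25492, is a provisional small Cajal body RNA gene. Limma called 1 of 13531 genes, and 707 had an unadjusted p under 0.05 against 676.6 from chance alone. It (ENSMUSG00000088008) was named here after its values were seen because the rule leaves out provisional symbols, with a log2 fold change of −3.15 (SE 0.444, limma adjusted p = 0.0459). Its FPKM was 1.55 ± 2.28 (SD, n = 4) in hM3Dq IP and 17.3 ± 6.55 (SD, n = 7) in control IP. The 7 nuclear-encoded noncoding RNAs described under the flagged results were also lower in hM3Dq IP (median −1.93). Whether Gm25492 RNA was carried on ribosomes was not tested. The call was lost when any of hM3Dq mice 1, 3 or 4 or control mice 1, 2, 4, 6 or 7 was left out. Leaving out control mouse 3 or 5 gave 2 genes each, and a pseudocount of 0.1, no filter, quantile normalization, eBayes without the trend and a block on mouse number each gave 0 by limma, with 676 to 916 at an unadjusted p under 0.05. The fit with that block also held fewer control mice, so its count does not show what the block alone did.

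The 10 named genes with the smallest p-values in this comparison did not pass. Nnat, an imprinted gene of developing neurons, had the smallest adjusted p, with a log2 fold change of −1.20 (SE 0.23, limma adjusted p = 0.277) and an FPKM of 616 ± 89 (SD, n = 4) in hM3Dq IP against 1468 ± 433 (SD, n = 7) in control IP. The values were −1.85 for Ccnb1ip1, 1.01 for the microtubule gene Ckap5, −1.93 for Rn7sk, −0.74 for the mitochondrial ribosomal gene Mrpl23 and 0.88 for Zfp521. For the interferon-induced gene Ifitm3 it was −2.25, for the smooth-muscle gene Myl9 −1.36, for Manbal −0.85 and for the transcription factor Zic1 1.14, with limma adjusted p-values up to 0.81 over the 10. Nnat (chromosome 2, 157560078 to 157562522) lies within Blcap on the opposite strand, and the table lists both.

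None of the genes fixed in advance passed the test between the IPs (limma), and Npy alone of them had an unadjusted p under 0.05, at 0.0397. Pmch differed by −0.30 (SE 0.488), Fos by 0.35 (SE 0.335), Agrp by −0.76 (SE 0.397), Npy by −1.56 (SE 0.694), Pomc by −0.69 (SE 0.51), Vegfa by −0.14 (SE 0.248) and Plvap by 0.16 (SE 0.43) on the log2 scale. The receptor gene of MCH, Mchr1, differed by −0.36 (SE 0.478) at an FPKM of 1.34 ± 0.951 against 2.5 ± 2.62, and the limma adjusted p-values of these 8 genes and Chrm3 (0.28) ran from 0.919 to 0.985. The tanycyte gene Rax was below the filter in every comparison. Fos averaged 12.6 ± 2.91 (SD, n = 4) in hM3Dq IP and 10.4 ± 4.03 (SD, n = 7) in control IP.

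No gene list was called between the IPs of the genotypes by camera with an estimated correlation (0 of 31, with 2 at an unadjusted p under 0.05). The 2 lists with the smallest adjusted p, 0.257, were arcuate dopamine neurons and mural cells. All 5 dopamine genes were lower in hM3Dq IP; 0 passed over all genes and 4 adjusted over the list alone, the synthesis genes Th (−0.74) and Ddc (−0.69) and the transporters Slc18a2 (−0.88) and Slc6a3 (−1.36). All 5 were lower in hM3Dq input too (median −0.38, camera adjusted p = 0.338). Th had an FPKM of 27.6 ± 8.48 (SD, n = 4) in hM3Dq IP and 47.5 ± 18.1 (SD, n = 7) in control IP. With a preset correlation of 0.01 the adjusted p of this list was 0.000274, and 10 lists were called, all lower in hM3Dq mice and none with an estimated correlation. These were the dopamine, tanycyte, astrocyte, endothelial, mural, vascular leptomeningeal, erythroid, ribosomal protein, mitochondrially encoded and nuclear oxidative phosphorylation lists.

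Other neuronal lists had median differences close to 0 or negative in the hM3Dq IP, and 0 members passed over all genes. The medians were 0.17 for lateral hypothalamic peptide neurons (mean −0.04, test positive), −0.34 for AgRP neurons, −0.35 for POMC neurons, 0.12 for kisspeptin and tachykinin neurons, 0.05 for other arcuate peptide neurons (mean −0.12, test negative), −0.33 for ventromedial neurons and 0.15 for pan-neuronal genes. Adjusted over the list alone, Sst (−0.91), the somatostatin gene, was the 1 member that passed in these 7 lists. Without control mouse 5 the median of kisspeptin and tachykinin neurons was −0.04. For immediate early genes the median was 0.10, with 22 of 31 members higher, none past the test and a camera adjusted p of 0.682. The camera adjusted p of these 8 lists ran from 0.426 to 0.926.

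Glial, vascular and barrier lists did not pass the set test between the IPs, and 0 members passed over all genes. The medians were −0.31 for tanycytes, −0.23 for ependymal cells, −0.27 for astrocytes, −0.25 for oligodendrocytes, 0.06 for oligodendrocyte precursors (mean −0.06, test positive), −0.19 for microglia and macrophages and −0.43 for endothelial cells. They were −0.87 for mural cells, −1.33 for vascular leptomeningeal cells, −0.49 for choroid plexus and −0.82 for erythroid cells. VEGF and angiogenic signalling had a median of −0.19, and tight junctions and barrier −0.08. Tanycytes, astrocytes and vascular leptomeningeal cells had lower medians still in hM3Dq input (−0.45, −0.33 and −1.49), and in the difference per mouse those of tanycytes and astrocytes were 0.18 and 0.10. Without control mice 1, 5 and 6 the difference per mouse had a median of 0.06 for tanycytes and −0.18 for astrocytes, with 12 of 15 astrocyte genes negative. Adjusted over the list alone, Myl9 passed in the mural list and Dcn (−1.33) and Igf2 (−2.25) in the leptomeningeal list. The 2 pars tuberalis and pituitary genes tested were too few for the set test and differed by −0.52 and −1.25, the latter passing over the list alone. Control mouse 5, whose IP stood apart, had the lowest astrocyte mean IP over input, −1.08. Without it the medians were −0.45 for astrocytes, −0.43 for ependymal cells, −0.42 for oligodendrocytes, −0.36 for microglia and macrophages, −0.20 for tight junctions and barrier and −0.02 for oligodendrocyte precursors.

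The remaining lists also gave no call. Of 77 ribosomal protein genes 70 were lower in hM3Dq IP, with a median of −0.24 and a camera adjusted p of 0.631. The medians were −0.13 for translation factors, −0.76 for mitochondrially encoded proteins, −0.12 for nuclear oxidative phosphorylation subunits and −0.08 for long noncoding nuclear RNAs (mean 0.03, test positive). They were −0.02 for heat shock and endoplasmic reticulum stress, −0.01 for glucocorticoid and fasting response, 0.11 for the circadian clock and 0.17 for sex-linked genes. Adjusted over the list alone, Chac1 (1.02), a gene of the stress response, was the 1 member of these 9 lists that passed. Without control mouse 5, whose IP stood apart, 51 of 77 ribosomal protein genes were lower and the medians were −0.06 for ribosomal proteins, −0.01 for translation factors, −0.29 for mitochondrially encoded proteins and −0.15 for glucocorticoid and fasting response. In this comparison the median 95% interval of a gene reached 0.558 to either side on the log2 scale.

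Input RNA gives the background of the genotype comparison. Limma called 0 of 13512 genes between hM3Dq and control input, with 613 at an unadjusted p under 0.05 and a smallest adjusted p of 0.921. The smallest p-value belonged to the collagen hydroxylase gene P4ha3 (−1.49, SE 0.275, limma adjusted p = 0.921). It was followed by Tmed3 (−1.33), Fam19a1 (−1.08), the chaperone gene Dnajc21 (0.89), the histone gene H3f3a (0.83), Adi1 (−0.76), Ifi27 (−1.46), Banf1 (−1.22), Aftph (−0.87) and the matrix Gla protein gene Mgp (−2.19). Pmch differed by −0.88 (SE 0.481), Npy by −1.32 (SE 0.58), Pomc by −0.43, Agrp by −0.03, Fos by −0.14, Vegfa by 0.04, Plvap by −0.12 and Chrm3 by −0.16, all with a limma adjusted p of 1. Camera called 0 of 31 lists, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.32, which astrocytes (median −0.33), tanycytes (−0.45), POMC neurons (−0.51) and vascular leptomeningeal cells (−1.49) shared. With a preset correlation these 4 lists were called, all lower in hM3Dq input. Leaving out control mouse 3 gave 1 called gene.

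Whether the enrichment in the IP itself differed between genotypes was tested on the IP over input difference of each mouse. Limma called 0 of 14582 genes, with 448 at an unadjusted p under 0.05 against 729.1 from chance alone, and a smallest adjusted p of 0.908. The 10 named genes with the smallest p-values were Ccnb1ip1 (−1.97), Rps27l (−1.63), Smim11 (−1.20), Med30 (−1.66), Rn7sk (−1.97), the glycosylation gene Rpn1 (−1.44), Tmem94 (−1.92), the RNase P subunit gene Rpp21 (−1.55), Rhoj (−1.82) and Triobp (1.84), with limma adjusted p-values from 0.908 to 0.999. Pmch had a difference of 0.58 (SE 0.345), Fos of 0.48 (SE 0.496), Agrp of −0.73 (SE 0.486), Npy of −0.24, Pomc of −0.27, Vegfa of −0.18, Plvap of 0.28, Mchr1 of −0.39 and Chrm3 of 0.44, with a limma adjusted p of 0.999. Camera called 0 of 31 lists, with 3 at an unadjusted p under 0.05 (arcuate dopamine neurons, VEGF and angiogenic signalling, and circadian clock, adjusted p = 0.482). With a preset correlation the erythroid, ribosomal protein and mitochondrially encoded lists were called, all lower in hM3Dq mice. A gene's median 95% interval reached 0.842 to either side, and leaving out hM3Dq mouse 5 gave 1 called gene.

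The authors' own ratio test, as deposited, gave 492 of 17440 genes with an unadjusted p under 0.05, 219 higher and 273 lower in hM3Dq mice, where chance alone gives 872. After Benjamini-Hochberg adjustment of the deposited p-values the smallest was 0.163. Of the 492 genes, 441 were tested here on the log2 scale, 440 had the same sign and 188 had an unadjusted p under 0.05. The deposited log2 fold changes were 0.59 for Pmch, 0.34 for Fos, −0.86 for Agrp, −0.68 for Npy, −0.47 for Pomc, −0.05 for Vegfa and −0.35 for Rax. They were −1.24 for Plvap, −2.03 for Mchr1 and −0.47 for Chrm3, which are low in FPKM, and Plvap and Chrm3 had the opposite sign on the log2(FPKM + 1) scale.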

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

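The 7 tests of the depleted RNAs in the last 2 paragraphs, and the fits without control mice 1, 5 and 6, were chosen after the result was seen. In 124 groups of libraries or mice, 9 held a value far from the rest of its group, where chance alone gives about 1 in 20 groups, or 6.2. The summed FPKM of hM3Dq IP 3 was 411400, against 392300 to 393200 in the other hM3Dq IPs. The mitochondrially encoded share of control IP 5 was 0.6399%, against 0.04707% to 0.1467%. Fos was at an FPKM of 8.247 in hM3Dq IP 3, against 13.73 to 14.44, and at 2.741 in control IP 5, against 7.815 to 15.11. Fosb was at 3.409 in hM3Dq IP 3, against 7.936 to 8.47. Vegfa was at 25.95 in hM3Dq input 4, against 7.213 to 8.848. Plvap was at 2.46 in hM3Dq input 1, against 0.9129 to 1.029. Rps27 was at 566 in control IP 5, against 136.5 to 181.4. The mean log2 IP over input of oligodendrocyte genes was −1.49 in control mouse 5, against −0.425 to 0.0411.

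Other splits of the same mice were fitted for each count of called genes. For IP against input in control mice, 1 of 64 swaps of IP and input within mice gave as many genes, the real one, with 678 genes against 84 in the highest other. That share is under the 0.05 set beforehand, so chance is an unlikely source of the count. No smaller share is possible with 64 swaps. For the hM3Dq mice, the 8 swaps are too few for a share under 0.05; 1 of 8, the real one, gave 1338 genes and the highest other 0. Between genotypes chance was not excluded: 5 of 100 splits gave at least the 1 gene found in the IP, and the highest other, of control mice 1, 2, 4 and 5 against the rest, gave 12. That count may come from structure among the mice or from chance, since it rests on 1 split and its source was not tested. For input and for the difference per mouse the splits say nothing about chance, because any split reaches the real count of 0 limma calls (613 and 448 genes at an unadjusted p under 0.05): 100 of 100 and 100 of 100 did, with 2 and 1 in the highest other.

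Ribosomal protein transcripts were lower in the IP than in the input, with medians of −0.78 in control and −0.96 in hM3Dq mice, though camera called the list in neither (adjusted p = 0.214 and 0.115) and control mouse 5 had a mean of 0.12. Length was that of each gene's longest annotated transcript, with a median of 1106 nt for the ribosomal protein genes. The match therefore cannot decide for shorter transcripts of these genes. Length so measured and level did not account for the pattern. Of 10000 random lists matched on both, which do not carry the correlation between ribosomal protein genes, the 2.5th percentile of the medians was −0.0626 in control and −0.15 in hM3Dq mice. Scaling did not account for it either, since the medians closest to 0 under other scalings were −0.76 and −0.97. Translation factor transcripts, which are longer and also not called by camera (adjusted p = 0.201 and 0.115), had medians of −0.47 and −0.56, below the 2.5th percentiles of their own matched lists (−0.175 and −0.19), so a property shared by messengers of the translation machinery stays open as a candidate explanation. No biological cause was tested.

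Of 17 called noncoding or mitochondrially encoded RNAs with a log2 fold change below −3 in the IP of both genotypes, 16 were lower in hM3Dq IP than in control IP, with a median of −0.88. Pseudogenes and nuclear genes annotated as protein-coding were left out, among them Ccnb1ip1, whose value cannot be separated from that of the overlapping RNase P RNA gene, and the set was fixed after the values were seen. The mice's means, 2.84 ± 0.779 (SD, n = 4) against 3.92 ± 0.685 (SD, n = 7), had an exact permutation p of 0.0364, which for that reason does not exclude chance. More bulk RNA carried into the control IPs cannot be told apart from a smaller or no difference, since the mitochondrial list's IP over input gave an exact permutation p of 0.424 and control mouse 5 spread the values. Without control mice 1, 5 and 6 the median was −0.56, and genotype stays open as an untested explanation.

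The 7 nuclear-encoded RNAs among them were all lower in hM3Dq IP, with a median of −1.93, and the 10 mitochondrial ones had a median of −0.63 with 9 lower. For the nuclear-encoded RNAs, which include Rn7sk, Rmrp and Bc1, the median without control mice 1, 5 and 6 was −2.13, which argues against those mice as the cause, while the exact permutation p of 0.00606 does not exclude chance for RNAs set apart after their values were seen. For the mitochondrial RNAs the median without those mice was −0.30 and the exact permutation p was 0.455, so both may account for it. The nuclear-encoded difference may also reflect genotype or the handling of the samples, and neither was tested. Library index numbers in the labels run consecutively by genotype, so if they follow the order of preparation, that order and genotype coincide in each comparison between genotypes.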

How the results depend on the processing

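The fits without libraries that stood apart were chosen after the data were seen. Of 1569 values of the 114 called named results under the alternatives, 1241 kept their direction and call, 328 kept their direction only and 0 reversed. Of 10219 values of uncalled results, 51 passed the threshold with the same direction, and 37 shifted by more than the SD of a mouse without passing, most of them with a pseudocount of 0.1. Of the named calls, 25 of 55 in control and 28 of 59 in hM3Dq mice held under all alternatives run. In the IP between genotypes, limma called 0 genes with a pseudocount of 0.1, 0 without a filter, 0 with quantile normalization and 0 without the trend (676 to 916 at an unadjusted p under 0.05), 3 in 1 fit of all 22 libraries and 2 without control mouse 5. With a replicate block on mouse number, 0 genes were called by limma (750 at an unadjusted p under 0.05). That fit left out the control mice whose number no hM3Dq mouse shared. Without the pairing block the hM3Dq IP against input count was 739. For IP against input, eBayes without the trend gave 312 genes in control and 592 in hM3Dq mice, 1 fit of all libraries 1395 and 678, and no filter 552 in hM3Dq mice. Leaving out 1 mouse at a time gave 0 to 2 genes in the IP between genotypes, 0 to 1 in the input, 330 to 768 in control IP against input, 575 to 836 in hM3Dq IP against input and 0 to 1 in the difference per mouse. These fits and the one with a block on mouse number hold fewer mice, and for the other changes the cause was not tested. With a preset correlation of 0.01, camera called 10 lists in the IP, 4 in the input, 8 in control and 8 in hM3Dq IP against input, and 3 in the difference per mouse. Quantile normalization gave 4 lists in control IP against input, and leaving out control mice 1, 5 and 6 gave 0 (5 at an unadjusted p under 0.05). Without those mice the medians of the immediate early and pan-neuronal lists were 0.698 and 0.501, against 0.564 and 0.365 with them. Those of the oligodendrocyte and AgRP neuron lists shrank to −0.186 and 0.126, from −0.479 and 0.517. The number of reads per library is unknown, so what depth limits could be set only relative to other libraries, over a 1.85-fold range.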

Other observations

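The counts by gene type and the test of list means per mouse were chosen after the data were seen. Chaperone and clock genes were among those higher in the IP than in the input. Of the heat shock and endoplasmic reticulum stress list, 3 of 14 genes rose in control and 3 of 13 in hM3Dq mice by limma, with 3 and 3 adjusted over the list alone. They were the cytosolic chaperones Hsp90aa1 (0.59 and 0.65) and Hspa8 (0.72 and 0.67) and the endoplasmic reticulum chaperone Hspa5 (0.70 and 0.73), while the set test gave camera adjusted p-values of 0.214 and 0.712. Of 16 clock genes, 2 rose in control and 4 in hM3Dq mice, with 3 and 5 adjusted over the list alone and camera adjusted p-values of 0.346 and 0.18. Nr1d1 rose by 0.79 and 0.95 and Bhlhe40 by 0.83 and 0.99, and Dbp (1.18) and Per1 (0.90) passed in hM3Dq mice. Of 12 alternatives in hM3Dq mice, 4 kept the Per1 and Hspa5 calls and 6 the Hsp90aa1 call, and of 16 in control mice, 7 kept the Bhlhe40 call. The mean IP over input of the clock list was 0.42 ± 0.0555 (SD, n = 4) in hM3Dq and 0.21 ± 0.13 (SD, n = 7) in control mice, above 0 in 4 of 4 and 7 of 7 mice. The difference had an exact permutation p of 0.0212 and a Benjamini-Hochberg adjusted p of 0.657 over 31 lists, and so did not pass.

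The limma calls between IP and input were also counted by type of gene. Long intergenic noncoding RNAs fell in 21 of 348 cases (6.03%) in control and 29 of 292 (9.93%) in hM3Dq mice, and protein-coding genes in 294 of 12107 (2.43%) and 518 of 11417 (4.54%). Antisense RNAs rose in 9 of 305 (2.95%) and 15 of 239 cases (6.28%), beside 279 (2.3%) and 640 (5.61%) of the protein-coding genes, and unprocessed pseudogenes fell in 7 of 25 (28%) and 7 of 20 (35%). No test compared these shares.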
